A study of Homo sapiens with 73 samples.

How the data were processed

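The samples were assigned to depot, donor and replicate from the labels. Per the submitters' processing notes, BWA, SAMtools 0.1.19, MACS2 and deepTools were used with genome build hg19; their roles and parameters are not given in the sources used here, including whether reads were shifted for the transposase. Nuclei were tagmented with a transposase kit, per the labels' protocols. The authors deposited a broad peak list for each library, numbered within the library, so peaks were called per library. Each deposited peak has an integer score, a fold enrichment (a ratio over the caller's background) and a −log10 p and −log10 q. The smallest deposited −log10 q was just above 1 in every list. These values are the authors' own and served only to filter or rank peaks within a list. No read counts are given, so the depth is unknown. A longer list may reflect more reads or more open regions, which these files cannot separate, and a base outside all peaks is not shown to be closed.

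Peaks of a library were merged and the covered bases computed on chromosomes 1 to 22 with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The interval arithmetic gave the same result as a base-by-base count in 20 of 20 simulated sets. The labels name the donor and the replicate library; the 2 libraries of a donor and depot were averaged, because they are not independent. No pair of replicate libraries was a repeat deposit, their Jaccard index reaching at most 0.567. Single values were compared with an exact two-sided permutation test over 70 assignments, whose smallest p is 0.0286. The donors pair the depots through the labels; across 50 kb windows the deviations of the abdominal and gluteofemoral units of a donor from the depot means correlated at 0.488, 0.416, 0.121 and 0.508. The main fits had no donor block, and the blocked fit was an alternative. The exact sign-flip test of 4 paired values cannot go below 0.125.

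Covered bases in windows and loci were scaled to the mean library total, averaged per unit and tested as log2(scaled covered bases + 500) with limma 3.58.1 in R 4.3.3 (trend in the variance prior, Benjamini-Hochberg threshold 0.05). Windows or loci with a mean below 500 scaled bases were left out. The log2 differences are on this scale and understate changes at low coverage. In simulated data for the depot comparison of 24680 windows, with 200 changed windows, 75.5% were recovered at a log2 difference of 1 and 95.0% at 1.5, with 2 and 6 false calls. The simulation used normal noise on the log2 scale without a floor, so simulated values can lie below that of an uncovered window. It also changed 200 windows at once, which eases the adjusted threshold. The shares recovered therefore do not show that an absence of passing windows excludes large differences.

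No annotation of hg19 was at hand, so the planned tests of all gene windows and of promoter occupancy were not run. Genes are instead represented by loci whose hg19 limits were written from general knowledge, extended by 5 kb on each side, so neighbouring HOX loci share bases. The limits of the 4 HOX clusters and of 26 genes were written before the data were examined, as were the gene lists, tests and most of the alternatives. Those of 41 HOX cluster genes were written after the format of the lists had been seen, but before any value at these loci. A further 159 loci of the same gene lists were written after the 50 kb windows, the depot-only segments and the first locus values had been seen. The limits were checked against gene lengths and chromosomes in a GRCh38 table, whose coordinates were not used. All 226 loci lay on the same chromosome. The length agreed within 2 kb or 10% for 24 of the 26, 31 of the 41 and 136 of the 159 loci; of the last group the 136 that agreed were kept, and of the first groups all were kept, HOXA3 among those whose length did not agree. The adjustment over the loci written before any value was seen was made the leading one after the calls of both sets, and the splits of the larger set, had been seen. The length check cannot detect a shift of both ends, so a locus value may include bases beyond the gene.

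Before the data were examined, the named items were set as the windows, HOX genes, list members and depot-only segments with the largest difference or length among those that passed, or the 5 of smallest p in each direction where none did, limited to the loci first written. ZIC1, the HOX genes outside that limit and the list members that did not pass are named in addition. List tests (camera, fry) needed at least 3 tested loci and ran on 14 of 16 lists; the mesothelial and skeletal myogenic lists had fewer and were not tested. Their background was the other loci, not all genes. Alternatives covered a stricter peak threshold (−log10 q of at least 5), equal numbers of peaks (83579 per list), each replicate or donor left out, the donor block, pseudocounts of 100 and 2000, no scaling, quantile normalisation, no coverage filter, no variance trend, windows of 20 kb and 100 kb, other segment rules, and loci extended by 1 kb or 20 kb. The 1 kb and 20 kb extensions, set beforehand for gene windows alone, were applied to the loci after seeing the data. Leaving out the shortest list, the added loci, the count of segments near HOX and positional loci, the list test without ZIC1, the HOX cluster ratios with a donor left out, and equal peak numbers or a left-out sample together with no coverage filter were also chosen after seeing the data.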

Results

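Chromatin accessibility was measured by ATAC-seq, which marks open DNA by transposase insertion, in cultured human adipose-derived stem cells, the fibroblast-like progenitors of fat cells. The cells came from subcutaneous fat of the abdomen and of the gluteofemoral region (buttock and thigh). For each of 4 donors both depots were sampled, with 2 replicate libraries per donor and depot, giving 16 libraries. The other 57 of the 73 samples of the series (ChIP-seq and ChIRP-seq of the same kind of cells) were not analysed here. Each library is a list of open regions (peaks) called on that library alone, in hg19 coordinates, and autosomes alone were used. The read depth of the libraries is unknown. The 2 libraries of a donor and depot were averaged, so that 4 abdominal units were compared with 4 gluteofemoral units (n = 4 per depot throughout), and every difference is given as gluteofemoral minus abdominal.

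The extent of open chromatin was compared first. Abdominal libraries had 133166 ± 12607 autosomal peaks (SD over donors, n = 4) and gluteofemoral libraries 120350 ± 16364, a difference of -12817 that had the same sign in 4 of 4 donors. The peaks covered 35.4 ± 3.68 Mb in abdominal units and 31.3 ± 6.13 Mb in gluteofemoral units. Neither difference passed the test (exact permutation test, two-sided, p = 0.314 for the number and p = 0.343 for the covered length). Within donors the differences had an SD of 8888 peaks and 3.83 Mb, and the covered length was also lower in 4 of 4 donors (the exact sign-flip test gave for each the smallest p possible with 4 pairs, which is above 0.05). Single libraries ranged from 83579 to 171885 peaks, the lowest being gluteofemoral replicate 2 of donor 3. The median peak width was 194.5 bp in abdominal and 191.75 bp in gluteofemoral units, averaged over donors.

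Whether depot or donor orders the libraries was asked from the bases that pairs of libraries shared. The Jaccard index of covered bases averaged 0.524 ± 0.0335 (SD over 8 pairs) for the replicate libraries of a donor and depot. It was 0.493 ± 0.0540 over the 16 pairs from the same donor and different depots, 0.467 ± 0.0451 over the 48 pairs from the same depot and different donors, and 0.457 ± 0.0530 over the 48 pairs that differed in both. Among pairs from different donors, sharing the depot added 0.00988, which was not beyond what relabelling the 8 units gave (exact permutation of the depot labels over 35 splits, two-sided, p = 0.171). These 35 splits include those that leave both depots of a donor on the same side, so the test does not use the donor pairing. The splits that part both depots of every donor were not compared for this index, so a small depot difference is not excluded.

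The HOX genes, transcription factors that hold the position of a cell along the body axis, were examined next, because adipose progenitors of different body regions are known to differ in HOX gene expression. Of the measured members, 3 had less peak coverage in gluteofemoral cells: HOXA5 and HOXA3 in the HOXA cluster on chromosome 7, and HOXD10 in the HOXD cluster on chromosome 2. Peaks covered 897 ± 208 scaled bases at HOXA5 in abdominal units and 315 ± 133 in gluteofemoral units. The corresponding values were 2307 ± 318 and 1231 ± 502 scaled bases at HOXA3, and 927 ± 104 and 338 ± 200 at HOXD10 (SD, n = 4). On the log2(scaled covered bases + 500) scale the differences were -0.78 (SE 0.16, limma adjusted p = 0.0166) for HOXA5, -0.74 (SE 0.19, adjusted p = 0.0329) for HOXA3 and -0.80 (SE 0.18, adjusted p = 0.0166) for HOXD10, each lower in 4 of 4 donors. The adjustment covered the 54 tested loci whose limits were written before any value at them was seen. The flank of the HOXA6 locus contains the limits of HOXA5. HOXA6 stood at 1039 ± 153 and 833 ± 293 scaled bases, a log2 difference of -0.23 (SE 0.17) that did not pass (adjusted p = 0.527). The difference at the HOXA5 locus is therefore not assigned to the gene itself, as opposed to its flanks. Adjusted over the list of HOX loci alone, 3 were lower and 0 higher. Adjusted over 161 loci, those added later included, HOXA3 no longer passed (adjusted p = 0.0736). With donor as a block it passed there too (adjusted p = 0.0311). HOXD9, the neighbour of HOXD10, stood at 1022 ± 150 and 508 ± 331 scaled bases, a log2 difference of -0.65 (SE 0.21) that did not pass (adjusted p = 0.0894). The flank of the HOXD10 locus contains the limits of HOXD9, so these loci share bases and are not separate signals. In the other direction HOTAIR, a long non-coding RNA gene of the HOXC cluster, stood at 360 ± 316 scaled bases in abdominal and 856 ± 163 in gluteofemoral units, higher in 4 of 4 donors, a log2 difference of 0.72 (SE 0.23) that did not pass either (adjusted p = 0.0894). Its locus overlaps that of HOXC11, which was below the coverage minimum and is named after its values were seen, at 314 ± 315 and 670 ± 80.0 scaled bases and also higher in 4 of 4 donors, so the bases are not assigned to HOTAIR alone. The next largest positive values were 0.28 at HOXD1, 0.07 at HOXB3 and 0.05 at HOXA13, none past the threshold. The last 2 turned negative without scaling. Of the 29 HOX loci tested, 22 had a negative and 7 a positive difference, with a median of -0.12. Without donor 3, 15 of 30 were negative and 15 positive, with a median of -0.0103. Mural and smooth muscle markers also had a negative median (-0.22 over 6 loci, none past the threshold). With donor as a block, as the shared donors allow, HOXD9 (adjusted p = 0.0254) and HOTAIR (adjusted p = 0.0120) also passed, making 4 loci lower and 1 higher. Without donor 1 or without donor 3 none of the 54 loci passed in either direction. Adjusted over the HOX list alone, 3 loci were lower without donor 3, with a smallest adjusted p of 0.0473, and 0 without donor 1. Without the libraries numbered 1 a single locus passed over the 54, and without the shortest list 3 did. With equal peak numbers or the stricter peaks none passed, HOXA5 and HOXD10 then falling below the coverage minimum. With equal peak numbers and no minimum, a combination chosen after seeing the data, the log2 differences were -1.03 (SE 0.13, adjusted p = 0.00114) for HOXA5, -0.93 (SE 0.15, adjusted p = 0.00360) for HOXD10 and -0.64 (SE 0.22, adjusted p = 0.148) for HOXA3.

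**Figure D1:**
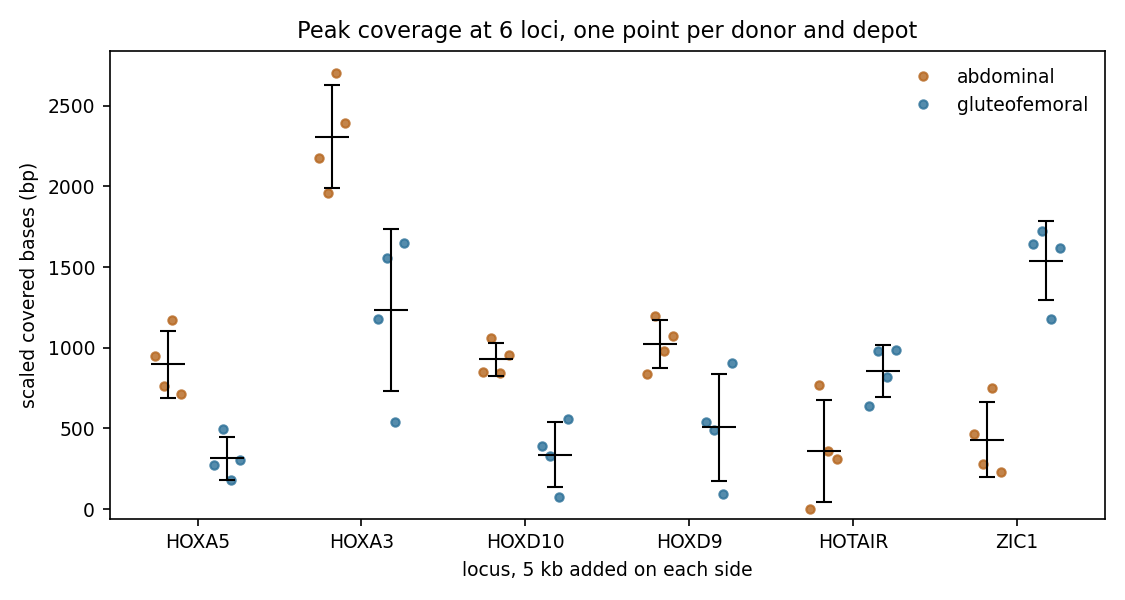
Scaled covered bases (bp, vertical axis) at 6 loci extended by 5 kb, with 1 point per donor in each depot; black lines give the mean and SD over 4 donors. HOXA5, HOXA3 and HOXD10 lie lower in gluteofemoral cells and passed the test. HOXD9 and HOTAIR did not pass without the donor block, and ZIC1 was added after its region had been seen.

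The HOX clusters as wholes were compared by the share of each cluster that peaks covered. The HOXA cluster was covered over 5.86% ± 0.723 in abdominal and 4.11% ± 1.77 in gluteofemoral units, and the HOXD cluster over 4.56% ± 0.615 and 3.37% ± 1.32; both were lower in 4 of 4 donors. Without donor 3 the HOXA difference was -0.886 percentage points, against -1.75 with all donors. The HOXB cluster stood at 2.47% ± 0.745 and 2.07% ± 0.825, and the HOXC cluster at 3.49% ± 1.001 and 3.36% ± 1.47. No cluster passed the test (exact permutation test, two-sided, adjusted over the 4 clusters, p = 0.343 for HOXA and HOXD, p = 0.648 for HOXB and p = 0.914 for HOXC). As a ratio to the genome-wide covered share, the HOXA cluster stood at 4.77 ± 0.375 in abdominal and 3.64 ± 1.15 in gluteofemoral units, lower in 4 of 4 donors, with an unadjusted p of 0.0286, the smallest this test can give (adjusted p = 0.114). Without donor 3, left out here after the ratio had been seen, the difference of -1.13 shrank to -0.393. On the same scale the HOXD cluster stood at 3.71 ± 0.173 and 2.98 ± 0.630, lower in 3 of 4 donors (adjusted p = 0.229).

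Segments open in both libraries of all 4 donors of a depot and in no library of the other depot were sought across the genome. No segment of at least 200 bp met this in either depot. The longest abdominal-only segment measured 199 bp, on chromosome 2 at 3526858 to 3527056. The next, of 193 bp, lay on chromosome 7 at 27175591 to 27175783, between HOXA4 and HOXA5 and reaching into the 5 kb flank of HOXA5. Abdominal-only segments of 144 bp, 123 bp and 117 bp followed on chromosome 17 from 30124885 to 30125028, chromosome 4 from 184949958 to 184950080 and chromosome 2 from 125097372 to 125097488. The 5 longest gluteofemoral-only segments were a segment of 140 bp on chromosome 12 from 116008327 to 116008466, segments of 118 bp (chromosome 3, 147126997 to 147127114, in the 5 kb flank of ZIC1) and 103 bp (chromosome 3, 147111153 to 147111255), a segment of 76 bp at TBX15 (chromosome 1, 119531017 to 119531092), and a segment of 62 bp on chromosome 3 from 9258564 to 9258625. What lies at the segments with no gene named was not determined, since no hg19 annotation was at hand. With no minimum length, 166 abdominal-only and 20 gluteofemoral-only segments were found. With equal peak numbers these counts were 79 and 20. A gluteofemoral-only segment must be covered in the shortest list, that of gluteofemoral replicate 2 of donor 3. The larger abdominal count is therefore not read as more depot-specific opening.

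**Figure D2:**
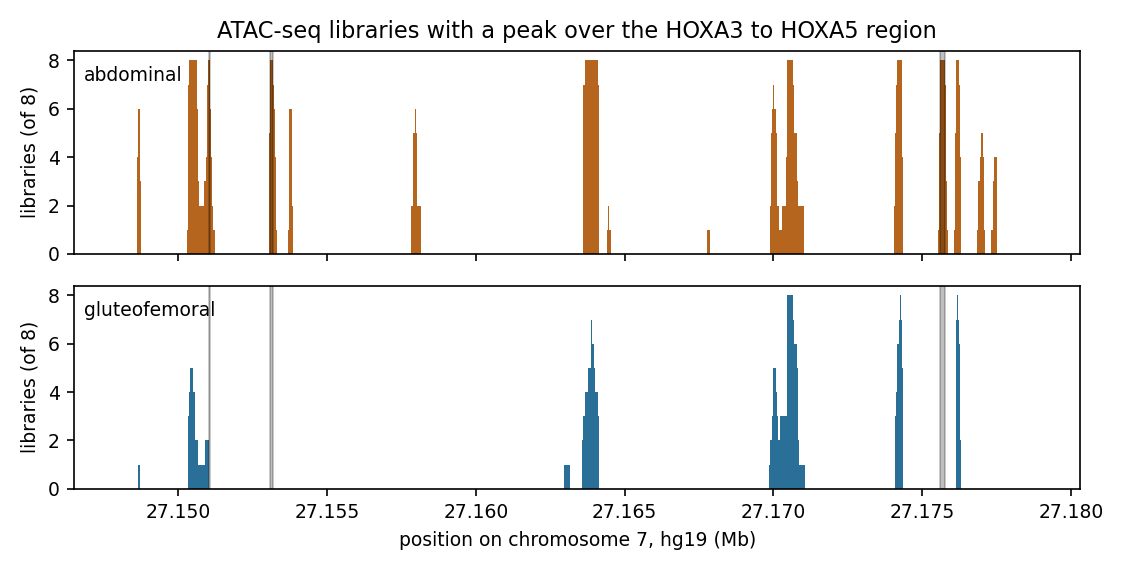
Number of abdominal (top) and gluteofemoral (bottom) libraries, of 8 each, with a peak at each position (vertical axis) over chromosome 7 from 27148034 to 27178783 (horizontal axis, Mb, hg19). Grey bands mark the 3 abdominal-only segments, covered by peaks in 8 abdominal and 0 gluteofemoral libraries.

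Windows of 50 kb tiling the autosomes were then tested without regard to genes. Of 24680 windows with enough coverage, 0 passed in limma after adjustment. An unadjusted p under 0.05 was found in 992, fewer than the share of 0.05 that chance gives. This fit does not use the donor pairing. The 5 windows of smallest p in each direction are given although they did not pass. The window of smallest p, on chromosome 3 from 147100001 to 147150000, overlaps ZIC1, a zinc finger transcription factor; peaks covered 740 ± 416 scaled bases of it in abdominal and 2744 ± 509 in gluteofemoral units, a log2 difference of 1.43 (SE 0.20, adjusted p = 0.152), higher in 4 of 4 donors. Further windows with higher coverage in gluteofemoral cells in 4 of 4 donors lay on chromosome 13 from 73750001 (log2 difference 1.03, SE 0.15), chromosome 8 from 136150001 (0.98, SE 0.19), chromosome 12 from 116000001 (0.70, SE 0.13) and chromosome 1 from 93200001 (0.64, SE 0.14). Lower coverage in 4 of 4 donors was found in windows on chromosome 20 from 59050001 (-0.90, SE 0.18), chromosome 7 from 26850001 (-0.80, SE 0.16), chromosome 4 from 90300001 (-0.73, SE 0.16), chromosome 1 from 58300001 (-0.63, SE 0.15) and chromosome 9 from 81300001 (-1.15, SE 0.27). With donor as a block 3 windows passed, all with more coverage in gluteofemoral cells: those on chromosomes 3, 8 and 13 named above (adjusted p = 0.0376 for each). In that blocked fit 2365 windows had an unadjusted p under 0.05. Of the other splits that part both depots of every donor, the highest gave 1627. Such splits number 8 with the depots included, too few for a share under 0.05.

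The remaining gene lists brought the loci tested to 161, the HOX loci included, most of them given limits only after the windows, segments and HOX values had been seen. ZIC1, a member of the list of positional and limb transcription factors, had 430 ± 234 scaled covered bases in abdominal and 1539 ± 246 in gluteofemoral units, a log2 difference of 1.16 (SE 0.17, limma adjusted p = 0.00204 over the 161 loci), higher in 4 of 4 donors. It was adjusted together with loci chosen after its window had been seen. Adjusted over the loci and the 50 kb windows together, no locus passed (limma adjusted p = 0.131 for ZIC1, 0.976 for HOXA5 and HOXD10). In this joint adjustment 1 locus passed with equal peak numbers and 1 without donor 3, and none in the other alternatives. Of the 35 positional loci tested, 1 was higher and 0 lower, both adjusted over the list alone and over the 161 loci. Members of this list that did not pass, named after their values were seen, were the homeobox gene EN1 (log2 difference 0.40, SE 0.13), PRRX1, a mesenchymal homeobox gene (-0.43, SE 0.14), and the T-box genes TBX5 (-0.55, SE 0.22) and TBX15 (0.22, SE 0.12; negative with the stricter peaks). With donor as a block 2 of the 161 loci were higher, ZIC1 (adjusted p = 0.00291) and HOTAIR (adjusted p = 0.0268), and 4 were lower, HOXD10, HOXA5, HOXA3 and PRRX1 (adjusted p = 0.0311 for PRRX1), against 1 and 2 without it. The limma fry test for change in either direction passed for this list (adjusted p = 2.88e-05, and 0.0243 with the donor block), but without ZIC1 its unadjusted p was 0.0672. The list did not pass in this test with the stricter peaks, without scaling, or in at least 1 fit with a sample left out. The directional p was 0.910 with ZIC1 and 0.503 without it.

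Outside the HOX and positional lists, no list had a member past the threshold, over all loci or adjusted over the list alone. The adipogenesis list had 6 loci higher and 10 lower in value, led by CEBPA, an adipogenic transcription factor (log2 difference 0.34, SE 0.12, adjusted p = 0.113 over the 54 loci). The median log2 difference was -0.04 for 9 adipose progenitor markers, -0.01 for 16 extracellular matrix loci, -0.03 for 13 WNT, BMP and TGF-beta loci, -0.08 for 9 waist-hip ratio loci, 0.06 for 4 steroid hormone loci, -0.05 for 4 Polycomb loci and -0.03 for 9 inflammatory loci. Among markers of other cell types, the median was -0.22 for 6 mural and smooth muscle loci, of which 5 were lower in value (MCAM at -0.43, SE 0.17; MYH11 at -0.56, SE 0.23), -0.20 for 3 epithelial loci, -0.03 for 5 endothelial loci and -0.01 for 6 leukocyte loci. Without donor 3 the median was -0.0699 for the mural and smooth muscle loci, 4 being lower and 2 higher in value, and -0.0311 for the epithelial loci. In limma's camera test 0 of the 14 lists passed with the preset or with an estimated correlation; the HOX list alone had an unadjusted p under 0.05 (0.00933, adjusted p = 0.131; adjusted p = 0.927 with an estimated correlation), which was 0.382 without donor 3. The mean and the median of the adipogenesis and endothelial lists, and the camera direction and the median of the positional, extracellular matrix, inflammatory, leukocyte, adipogenesis and endothelial lists, had opposite signs. Camera compares a list with the other loci, so its direction need not follow the sign of the list's own median.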

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

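All of the comparisons in this part with other splits of the units, and the tests of the explanations weighed, were chosen or written down after the results had been seen. Of 68 groups of values examined for a sample far from the others, 5 had one, where chance gives about 1 in 20. Among the 8 abdominal libraries, replicate 2 of donor 4 stood apart with 171885 peaks, the nearest having 136062, and with 48.5 Mb covered, the nearest having 36.2 Mb. In abdominal units, a low value of 75.4 scaled bases stood apart in the window on chromosome 8 from 136150001 (nearest 345), a low value of 585 in the window on chromosome 12 from 116000001 (nearest 713), and a high value of 1728 in the window on chromosome 1 from 58300001 (nearest 1165).

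The 3 HOX loci with less coverage in gluteofemoral cells, counted over the 54 loci that were made the leading set after the splits of the 161 had been seen, were weighed against chance and against differences between the peak lists. Of the 35 splits of the 8 units, 1 (the depots themselves) gave 3 or more loci past the threshold among the 54, the highest of the others giving 1; the donors pair the depots, and the 8 splits that part both depots of every donor, the highest other giving 0, are too few for a share under 0.05. With equal peak numbers and no coverage filter the median log2 difference of the 3 loci was -0.93 (median SE 0.15), against -0.78 with all peaks. The median thus did not shrink, though HOXA3 alone stood at -0.64. The equal lists are cut from the peaks in which the 3 loci were chosen, so a negative median was likely here too. Covered length also stayed lower in gluteofemoral units at equal numbers. Whether shorter gluteofemoral lists contribute is therefore not decided. Without donor 3, whose gluteofemoral list is the shortest, the median log2 difference of the 3 loci was -0.62 (median SE 0.16), and none of the 3 then passed. The single values were -0.62 for HOXA5, -0.67 for HOXD10 and -0.46 for HOXA3, against -0.78, -0.80 and -0.74 with all donors. The 3 loci were chosen with the other donors included, so a negative median was likely beforehand. Over all tested HOX loci, negative and positive differences were equally many without donor 3, as given above. How far that donor accounts for the calls stays open. The depot itself, and differences in cell composition or culture between the depots, stay open. The mural markers MCAM (-0.43) and MYH11 (-0.56) were also lower in 4 of 4 donors without passing. So were the epithelial marker KRT8 (-0.42) and loci of several other lists. The other mural loci stood at -0.32 (CNN1, lower in 2 of 4 donors), -0.12 (NOTCH3), -0.01 (CSPG4) and 0.04 (ACTA2). The median of the mural list likewise shrank without donor 3 (from -0.22 to -0.0699). Whether composition accounts for the HOX loci was not tested.

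Other results of the fits across many sites stood as follows against the splits. For the 3 calls over all 161 loci, 3 of the 35 splits gave as many, the highest other, which sets donors 1 and 3 against 2 and 4, giving 6; among the 8 splits that part every donor, too few for a share under 0.05, the highest other gave 0. For the 0 windows, the 0 segments of at least 200 bp and the 0 camera lists, all 35 splits give as many by construction, so nothing was tested there. The highest other split gave 6 windows, 6 segments and 1 list. For the 186 segments of any length 9 of 35 splits gave as many, the highest other giving 735, which is several times the depot count. That split keeps both depots of donor 2 on the same side, and likewise those of donor 4. What drives its count was not tested. Among the 8 splits that part both depots of every donor, the highest other gave 28. For the mixed fry test 6 of 35 splits gave 1 list or more, the highest other giving 2. With the donor block, the 5 loci and the 3 windows were matched only by the depots themselves, 1 of 8 splits that part every donor for each, the others giving 0; 8 splits are too few for a share under 0.05.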

How the results depend on the processing

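The alternatives leaving out the shortest list, adding loci and changing the locus flank were chosen after seeing the data. The differences in peak number and covered length, the Jaccard difference and the HOXA, HOXB and HOXD cluster shares kept their direction under every alternative run, except that HOXB turned to 0.0161 as a ratio to the genome-wide share without donor 3, also chosen after seeing the data. With a donor left out their exact test cannot go below 0.1, and the adjusted p of a single cluster cannot go below 0.114 in any, so staying short of the threshold shows nothing there. The HOXC cluster difference (-0.135 percentage points) turned to 0.0498 with equal peak numbers and to 0.116 as a ratio to the genome-wide share, and ranged from -0.376 to 0.319 when a donor, replicate or library was left out. Equal numbers give no peak number difference by construction.

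The segment counts of 0 rose to 166 abdominal-only and 20 gluteofemoral-only at any length, which became 79 and 20 with equal peak numbers. They were 41 and 8 with at least 1 library of each donor, and 14 and 2 with at least 3 donors. Leaving out a donor, replicate or library gave 0 to 34 and 0 to 4, since fewer libraries must then meet the rule. Windows with more coverage in gluteofemoral cells numbered 1 with equal peak numbers, 1 with windows of 100 kb and 3 with donor as a replicate block, and 0 to 1 when a sample was left out. Loci with more coverage numbered 1 with the replicate block, 1 without the variance trend, 1 with the loci added later and 1 with windows of 20 kb, whose variance prior the loci share, against 0. Loci with less coverage numbered 3, but 0 with the stricter peaks and 0 with equal peak numbers (18 and 32 loci then being tested, against 54), 1 with a pseudocount of 100, 1 with a flank of 1 kb, 2 without scaling, 2 without the coverage filter (HOXA3 at adjusted p = 0.0638), 4 with the replicate block, 4 with a flank of 20 kb, and 0 to 4 when a sample was left out. Camera called 1 list, the HOX list with 5 loci left, with the stricter peaks (adjusted p = 0.00156; adjusted p = 0.439 with an estimated correlation). The mixed fry test called 0 lists with the stricter peaks, 0 without scaling, and 0 to 2 when a sample was left out. Where no construction is named, the cause was not tested.

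Among the named loci, ZIC1 passed in all 17 alternatives that gave it a value (adjusted p 0.000237 to 0.0382 over all loci) and fell below the coverage minimum with the stricter peaks. HOXA5 passed in 11 of 15, HOXD10 in 9 of 15 and HOXA3 in 9 of 18. HOXB3 turned to -0.00733 without scaling and ranged from -0.0626 to 0.196 when a sample was left out. HOXA13 turned to -0.0547 without scaling and -0.0222 with a 20 kb flank, and ranged from -0.104 to 0.364. TBX15 turned to -0.0226 with the stricter peaks. Without scaling the median window difference was -0.124, against 0.00424 with it. With the replicate block HOXD9 and HOTAIR were gained among the 54 loci, and HOTAIR, HOXA3 and PRRX1 among the 161, which made 2 with more and 4 with less coverage, against 1 and 2; with the 3 windows above, these were all the calls of windows, loci and lists that it changed. The gene window and promoter alternatives were not run for lack of an hg19 annotation. The unknown depth limits all results.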

Other observations

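The observations in this part, and their tests, were all chosen after the segments had been seen. Some of the depot-only segments, all of them short, lay near HOX and positional transcription factor genes. Of the 186 segments, 11 (10 abdominal-only and 1 gluteofemoral-only) lay within 5 kb of the 57 such loci whose limits were written before any value at them was seen, which span 1.13 Mb with their flanks; most of the 186 lay elsewhere, and 2 of the 11 measured 1 bp and 6 bp. On chromosome 7 the abdominal-only segments were between HOXA4 and HOXA5, reaching into the 5 kb flank of HOXA5 (27175591 to 27175783), and at HOXA3 (27153093 to 27153176 and 27151034 to 27151058). On chromosome 2 they were in the 5 kb flanks of HOXD3 (177039255 to 177039328) and HOXD10 (a single base at 176981271). On chromosome 12 they were at TBX5, a forelimb T-box gene (114844184 to 114844279 and 114838917 to 114838952), and on chromosome 3 at SHOX2, a limb homeobox gene (157815913 to 157815945 and 157816019 to 157816024). At TBX15, a T-box gene also on the waist-hip ratio list, an abdominal-only segment (chromosome 1, 119530253 to 119530304) lay beside the gluteofemoral-only segment (119531017 to 119531092).

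A hypothesis from these values is that stable differences in accessibility between the depots may be enriched at genes of positional identity. Of the 35 splits of the 8 units, 1, the depots themselves, gave 11 or more segments within 5 kb of these loci, and the highest other gave 1; the 8 splits that part both depots of every donor, the highest other giving 0, are too few for a share under 0.05. With equal peak numbers the depots gave 6 and the highest other split 1, again 1 of 35 splits with as many. The equal lists hold part of the same peaks, and 79 abdominal-only against 20 gluteofemoral-only segments remained genome-wide. Whether shorter gluteofemoral lists contribute is therefore not decided. At the 122 loci of the other lists, spanning 9.77 Mb, the depots gave 0 segments. Many other splits also gave 0 there, the highest giving 9. Most of these loci were written after the segments had been seen, so this 0 is no evidence of a contrast. Several of the segments share a locus and are not independent, and the idea came from the same data, so it stays a hypothesis; at the 24 positional loci added later, 2 gluteofemoral-only segments lay, both within 5 kb of ZIC1, which had been seen first.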
